A study of Mus musculus with 22 samples.

How the data were processed

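The series holds 22 mouse samples, 10 of poly(A) RNA and 12 of chromatin immunoprecipitation followed by sequencing (ChIP-seq). BV2 is an immortalised mouse microglial cell line. Its cells had been transduced with a lentiviral vector that was empty, or that carried an N-terminal fragment of human huntingtin with 15 glutamines (the wild-type fragment) or 128 glutamines (the mutant fragment). Each of the 3 constructs has 2 RNA libraries from different times after transduction. The ChIP-seq samples are 4 antibodies (against H3K4me2, PU.1, C/EBPα and C/EBPβ) in the same 3 constructs, 1 library each, labelled 24 h. The 4 primary-cell RNA libraries are adult brain microglia and bone marrow derived macrophages from mice with 7 (wild-type) or 175 (mutant) glutamines in both huntingtin alleles, 1 library each. Per the labels, microglia came from cortex, striatum and hippocampus through a Percoll gradient and a sort for CD11b-positive, CD45-low cells, and macrophages were grown from bone marrow in L-cell conditioned medium. The labels do not say whether libraries came from separate transductions, cultures or animals, so p-values measure only the spread between these samples, which may be technical.

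The times of the BV2 RNA libraries conflict. The first library of each construct is 24 h in both sources; the other is 6 h in the header of the expression table and 48 h in the labels. It is called the second time here, and no order of the 2 times is assumed.

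RNA values are RPKM (reads scaled to transcript length and to library size) for 31641 RefSeq transcripts of the mm9 assembly with 23953 gene symbols, in 1 table deposited by the authors. The submitters' processing notes name STAR 2.0.3e, HOMER and edgeR for the RNA samples, and no read counts were used here. In the lowest values, RPKM times transcript length came out as whole multiples of 1 read for 100% of values within a tolerance of 0.1 reads. The steps gave an implied depth of 11.1, 13.2 and 13.7 M reads for empty-vector, wild-type-fragment and mutant-fragment cells at 24 h, and 14.0, 12.7 and 10.8 M at the second time. For microglia it was 34.3 and 28.8 M reads (wild-type and mutant), and for macrophages 30.2 and 47.8 M. Reads on gene transcripts, with 1 transcript per gene symbol, were fewer. They came to 3.63 to 4.71 M per BV2 library and 9.85 to 24.6 M per primary library. Between 9515 and 10062 genes per library reached an RPKM of 1. A gene at an RPKM of 1 has few reads at this depth, and transcripts under 200 bases (micro-RNA and small nucleolar RNA entries) need only a few reads for a high RPKM, so they were counted separately. The counting of reads shared by near-identical genes is not given in the sources used here. Values for H2-D1, H2-K1 and H2-Q7, for Pilra, Pilrb1 and Pilrb2, for histone genes, for Hspa1a and Hspa1b and for Gapdh, which has many pseudogenes, are therefore uncertain.

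The ChIP-seq files are peak lists on mm9. Per the file headers, HOMER called peaks separately in each library at 4-fold over an input, 4-fold over the local signal and a p of 1e-04. The factor libraries were called at a false discovery rate of 0.001 and a fixed width of 131 to 149 bp, and H3K4me2 with variable widths (medians of 1318, 1233 and 1154 bp in empty-vector, wild-type-fragment and mutant-fragment cells). The input is named after another macrophage source in the headers, not after BV2 cells. The score that the authors deposited for each peak is 1 throughout, so peaks could not be ranked. Bowtie is also named in the submitters' processing notes. Total tags were 5.26 to 5.39 M for H3K4me2, 5.36 to 7.30 M for PU.1, 14.7 to 24.1 M for C/EBPα and 13.6 to 17.7 M for C/EBPβ.

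From these files, the transcript with the highest mean RPKM was kept for each gene symbol. Genes with an RPKM of 1 or more in at least 2 libraries of a fit were tested on the log2(RPKM + 1) scale, which understates the fold change of genes with low values. BV2 libraries were fitted with limma 3.58.1 (R 4.3.3) with construct and time as terms, 6 libraries and 2 residual degrees of freedom, so that the 2 times take the place of replicates and the error is the difference in construct effect between times. The primary libraries were fitted with genotype and cell type as terms, 4 libraries and 1 residual degree of freedom. There limma gave every gene the same standard error, 0.26, so these p-values rest on 1 spread shared by all genes. Adjusted p-values are Benjamini-Hochberg over all genes tested, and the threshold was 0.05. The genotype difference within microglia or within macrophages rests on 1 library each side and is given with no test.

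The 25 gene lists were fixed from general knowledge before the data were examined: myeloid transcription factors, homeostatic microglia, lysosome and damage-associated microglia, pro-inflammatory cytokines and mediators, Toll-like receptor and NF-kB pathway, interferon-stimulated genes, antigen presentation, alternative activation, complement and phagocytic receptors, oxidative stress response, endoplasmic reticulum stress and integrated stress response, heat shock chaperones, cholesterol biosynthesis, glycolysis, cell cycle, immediate-early genes, kynurenine pathway, and markers of monocytes and border macrophages, neutrophils and granulocytes, lymphocytes, neurons, astrocytes, oligodendrocytes, endothelial cells and fibroblasts. In BV2 cells, the 17 lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, which compares a list with all other genes, adjusted over lists. Beside it stand camera with the correlation estimated from the libraries, and fry, which asks whether the genes of a list move 1 way. With an estimated correlation camera rests on the 2 residual degrees of freedom, so it could hardly call any list. Its higher p-values therefore do not show that correlation between genes removes a call. The estimated correlation was -0.041 for antigen presentation and -0.022 for oxidative stress genes, below the preset value, but 0.88 for cholesterol biosynthesis genes. In primary cells, a list's median difference is given with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. That percentile describes these libraries and is not a p-value.

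Also fixed before the data were examined were the main fits, most of the alternative settings and the rule for named genes. Htt, Spi1 (PU.1), Cebpa, Cebpb and Irf8 were always named. In BV2 comparisons up to 12 genes per direction were named by size of change among those past the threshold and changed the same way at both times (8 for the wild-type fragment, 5 for time). Where fewer than 5 passed, those with the largest change at the less changed time, among genes changed at least 2-fold at both times, were named and are said to be chosen by size. Up to 10 genes per direction were named within each primary cell type, among genes with an RPKM of 5 or more in at least 1 library, and 10 between cell types. Up to 4 members with the largest change were named in each list. A gene named outside the rule is said to be so, and 1 gene that the rule names is not reported here.

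Peaks were compared by overlaps of at least 1 bp with bedtools 2.31.1. Shares carry Wilson 95% intervals, which cover counting error only, and a chance level from moving the other list by 50 kb. Genes with a peak within 20 kb of the transcription start given in the expression table were compared with all other tested genes by Fisher's exact test, two-sided, adjusted over the family. These other genes were not matched on expression. The percentile among expression-matched random lists, planned to stand beside this test, is not given here. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used. The reference tables at hand are on another assembly, so no coordinate came from them.

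The steps were tested on simulated data with 200 changed genes in each of 5 simulations per fit. Simulated reads varied with a dispersion of 0.02, and each fold was the same at both times or in both cell types. The difference in construct effect between times, which is the error of the BV2 fit, was thus left out. The shares below therefore hold for such data and may overstate what the real fits can call. For the mutant fragment against the empty vector (10147 genes), 48.7% of 2-fold, 97.0% of 4-fold and 99.7% of 8-fold changes were called, and 13.7% of calls were false. Of the false calls 96.2% were transcripts under 200 bases, and 0.60% of calls were false without these. For mutant against wild-type primary cells (10576 genes) the shares called were 79.4%, 98.5% and 97.6%. There 14.7% of calls were false, or 2.58% without transcripts under 200 bases. Alternatives tried were other pseudocounts and filters, quantile normalization, 1 fit of all 10 RNA libraries, every transcript as its own feature, an intensity trend, no time term, leaving out each library, other windows and a stricter overlap. Leaving out transcripts under 200 bases, other gene sets and peaks of 1 construct alone were added after the data were seen. The last are peaks of mutant-fragment or empty-vector cells with no overlap in the other, whatever the wild-type fragment shows.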

Results

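The series measured gene expression and chromatin in myeloid cells that carry mutant huntingtin, the protein whose expanded glutamine tract causes Huntington's disease. BV2 cells, a mouse microglial line, were compared in 3 groups of 2 RNA libraries: with the empty vector, with the wild-type N-terminal fragment of 15 glutamines, and with the mutant fragment of 128 glutamines. The second library of each group has a time that the table's header gives as 6 h and the labels as 48 h, and it is called the second time. H3K4me2, a mark of promoters and enhancers, and the myeloid factors PU.1, C/EBPα and C/EBPβ were mapped in 1 BV2 library per construct. Microglia and bone marrow derived macrophages of wild-type and mutant mice gave 1 RNA library each. Implied depth lay between 10.8 and 14.0 M reads (M, mega) in BV2 cells and between 28.8 and 47.8 M in primary cells. Reads on gene transcripts were fewer, 3.63 to 4.71 M and 9.85 to 24.6 M.

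The first comparison, of the mutant fragment with the empty vector, asks what the mutant fragment changes in a microglial cell. Marco, a scavenger receptor of phagocytes, went from 0.64 and 1.05 RPKM (24 h and the second time) with the empty vector to 97.0 and 59.0 RPKM with the mutant fragment. Its log2 fold change on the log2(RPKM + 1) scale was 5.38 (SE 0.37), or 41.8-fold, and lay between 3.79 and 6.36 over 15 other settings. Il1a, the cytokine interleukin-1 alpha, rose from 4.49 and 1.78 to 66.4 and 34.3 RPKM, and Ebi3, a subunit of the cytokines interleukin-27 and interleukin-35, from 0.39 and 0.31 to 14.1 and 9.82 RPKM. Their folds were 12.5 and 9.49, and over the same settings their log2 fold changes lay between 2.72 and 4.03 and between 1.65 and 4.74. Pilrb1, Pilrb2 and Pilra, neighbouring genes for paired immunoglobulin-like receptors of myeloid cells, rose from 0.799 and 1.97 to 20.9 and 40.5 RPKM, from 0.350 and 0.951 to 10.4 and 19.6 RPKM, and from 1.40 and 2.27 to 14.8 and 31.0 RPKM. The lectin receptor genes Clec4n (dectin-2) and Clec4a1 rose 8.00-fold and 5.50-fold, and Nfkbia, the NF-kB inhibitor IκBα and itself an NF-kB target, rose 5.18-fold, from 2.00 and 3.18 to 14.1 and 21.3 RPKM.

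These 9 genes were the ones past the threshold among 10350 tested (limma, 2 libraries per construct, adjusted p between 0.0206 and 0.0396), each higher at both times. No gene was called lower, and 1584 genes had an unadjusted p under 0.05 in either direction. Marco lies at chromosome 1, 122371115 to 122401661 (mm9), Il1a at chromosome 2, 129125346 to 129135708, and Nfkbia at chromosome 12, 56590396 to 56593634. Pilra (138263180 to 138277506), Pilrb1 (138293375 to 138299277) and Pilrb2 (138307057 to 138312986) adjoin on chromosome 5, and their similar sequences leave the split of reads between them uncertain. Ebi3 lies on chromosome 17 at 56092046 to 56096445, and Clec4n (123179861 to 123197042) and Clec4a1 (122871866 to 122884637) lie on chromosome 6. The count was 0 with a pseudocount of 5 or with no filter on low values and 3 without the time term. It was 521 higher and 929 lower without the mutant-fragment library of 24 h, 1764 and 1526 without that of the second time, 129 and 100 without either wild-type-fragment library, 13 and 3 without the empty-vector library of 24 h, and 5 and 0 without that of the second time.

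**Figure D1:**
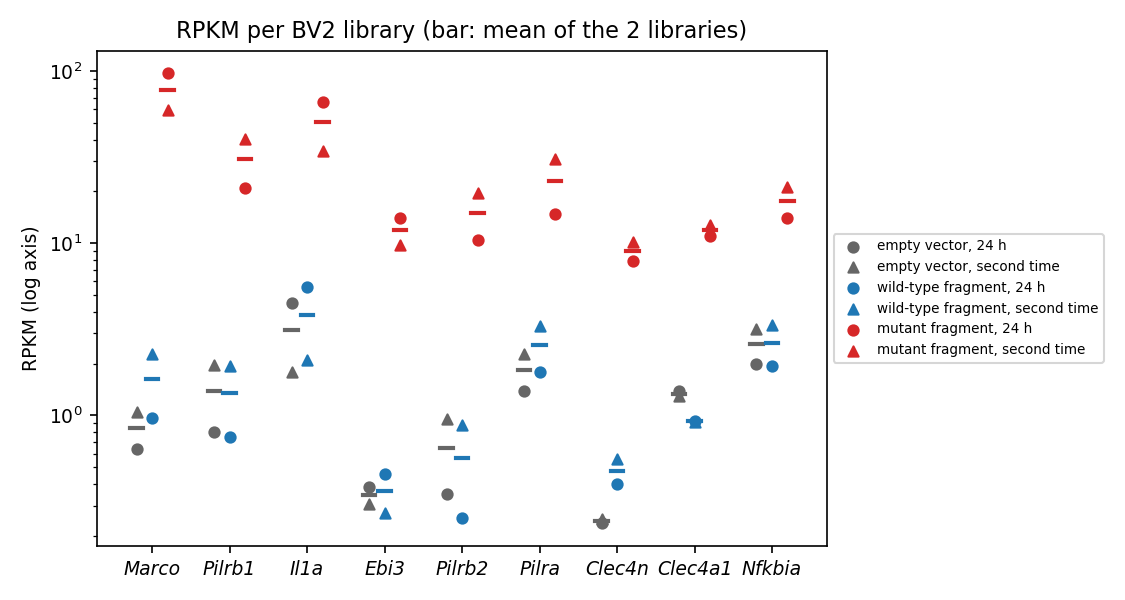
RPKM on a log axis of the 9 genes called higher with the mutant fragment, in each BV2 library (circles 24 h, triangles the second time, short bars the mean of 2 libraries). For every gene both mutant-fragment libraries lie above the other 4, as for Nfkbia at 14.1 and 21.3 RPKM against 1.93 to 3.37 RPKM.

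No gene passed as lower, so the lower genes are named by the size of their change. Bnip3, a mitophagy gene and hypoxia target, had 59.5 and 35.1 RPKM with the empty vector and 5.17 and 4.78 RPKM with the mutant fragment (log2 fold change -2.97, SE 0.25, adjusted p = 0.0557 in limma). Ankrd37, another hypoxia target, had 20.1 and 6.37 against 0.162 and 0.207 RPKM. Arg1 (arginase 1, a marker of alternative activation) had 189.7 and 22.5 against 1.34 and 4.88 RPKM, a log2 fold change of -4.17 with an SE of 1.21. Atp6v0d2, a subunit of the vacuolar proton pump, had 41.2 and 14.2 against 3.24 and 2.80 RPKM. Abcd2 (-2.90), a peroxisomal transporter, and Gpd1 (-1.95), a glycerol phosphate dehydrogenase, were also among the 12, and the other 6 were transcripts under 200 bases (Snord45b, Mir6948, Mir6985, Mir6970, Mir6987 and Mir7117). Across transcripts of 200 bases or more, 89 genes were at least 2-fold higher and 59 at least 2-fold lower at both times. At 24 h alone 485 were higher and 573 lower, and at the second time 222 and 273. Over these 9961 genes the differences at the 2 times had a Pearson r of 0.301 and a Spearman rho of 0.173, across genes, which are not independent replicates.

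**Figure D2:**
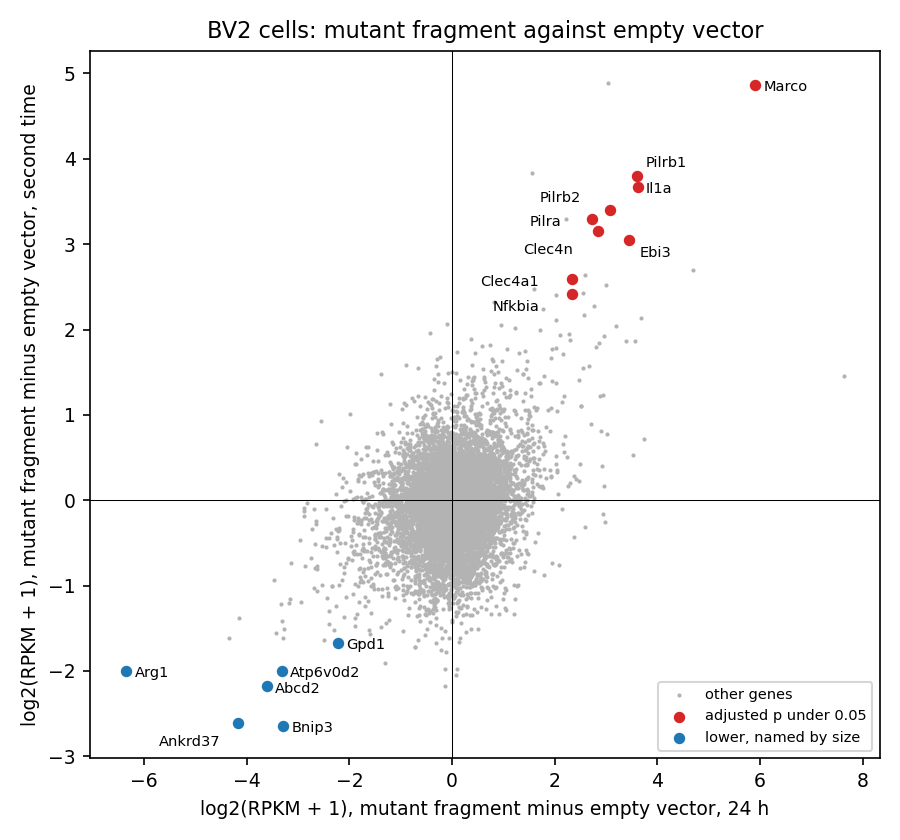
Log2(RPKM + 1) difference between mutant-fragment and empty-vector cells for each tested gene at 24 h (x axis) and at the second time (y axis). The 9 genes past the threshold (red) lie at upper right, and 6 lower genes named by size (blue), such as Bnip3 with a fitted change of -2.97, at lower left.

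The factors studied by ChIP-seq and huntingtin itself were always examined. Spi1, the gene of PU.1, had 26.9 and 28.7 RPKM with the empty vector, 25.8 and 30.3 with the wild-type fragment and 47.8 and 70.2 with the mutant fragment (log2 fold change 1.03 against the empty vector, SE 0.19, adjusted p = 0.170 in limma). Cebpb was at 51.6 and 37.1 RPKM with the empty vector and 149 and 52.4 RPKM with the mutant fragment (1.00, SE 0.29, adjusted p = 0.249). Cebpa (-0.64, SE 0.21, adjusted p = 0.283) and Irf8 (-0.44, SE 0.25, adjusted p = 0.466) did not pass either. The mouse Htt gene was at 3.97 and 2.86 RPKM with the empty vector and 3.80 and 3.79 RPKM with the mutant fragment (0.13, SE 0.18), and the expression table has no separate value for the human fragment.

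Of the 17 lists tested, that of inflammatory mediators had the highest median with the mutant fragment. Of 15 tested pro-inflammatory cytokines and mediators, 13 were higher at both times, with a median log2 fold change of 0.96. The chemokine gene Ccl4 had 6.45 and 9.59 RPKM with the empty vector against 58.8 and 59.7 RPKM, Ccl3 26.0 and 41.5 against 208 and 159.8 RPKM, and Tnf 1.86 and 3.30 against 15.9 and 18.3 RPKM (adjusted p over all genes 0.0694, 0.112 and 0.0557 in limma). Adjusted over the list alone, 9 of the 15 passed, all higher, beside 1 (Il1a) over all genes. In camera the list was raised (adjusted p = 6.14e-10), with adjusted p = 0.332 with an estimated correlation. Of 27 genes of the Toll-like receptor and NF-kB pathway (median 0.46), 13 passed adjusted over the list alone, 10 of them higher. They include the receptor gene Tlr2 (2.37) and the feedback genes Nfkbia (2.37), Nfkbiz (2.90) and Irak3 (2.09), which are known to restrain or shape NF-kB signalling. That list was also raised in camera (adjusted p = 6.83e-04, adjusted p = 0.332 with an estimated correlation, and 0.0929 without the mutant-fragment library of the second time).

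Antigen presentation and oxidative stress genes were higher as lists too. Of 16 antigen presentation genes (median 0.46, camera adjusted p = 2.96e-05, adjusted p = 0.332 with an estimated correlation), 5 passed adjusted over the list alone, all higher, with Cd40 (1.54), H2-K1 (1.46), H2-D1 (1.27) and H2-Q7 (1.19) as the largest changes. H2-K1, a class I histocompatibility gene whose reads may be shared with its relatives, had 54.5 and 29.4 RPKM with the empty vector and 154 and 81.0 RPKM with the mutant fragment. Of 18 oxidative stress genes (median 0.66, camera adjusted p = 8.18e-05, adjusted p = 0.332 with an estimated correlation), 8 passed adjusted over the list alone, all higher. Srxn1 (1.55), Slc7a11 (1.38) and Txnrd1 (1.10), which are known NRF2 targets, and Gpx1 (0.91) changed most, though none passed over all genes.

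Glycolysis and cholesterol genes were lower as lists. The 18 glycolysis genes had a median of -0.63 (camera adjusted p = 4.09e-05, adjusted p = 0.703 with an estimated correlation). The median difference was -1.22 at 24 h and -0.24 at the second time, and the list was not called without the mutant-fragment library of 24 h (adjusted p = 0.229). Ldha, lactate dehydrogenase A, had 408 and 389 RPKM with the empty vector and 124 and 305 RPKM with the mutant fragment, and Pdk1 (-1.08) and Pfkl (-0.98) followed Bnip3 in size. Adjusted over the list alone 2 passed, Pfkfb3 (0.82, named after its value was seen) as higher and Bnip3, which is no glycolytic enzyme gene, as lower. For the 18 cholesterol biosynthesis genes the median was -0.54 (camera adjusted p = 0.00319, adjusted p = 0.719 with an estimated correlation) with 1 passing, lower, adjusted over the list alone. Their median difference was -1.29 at 24 h and 0.17 at the second time, and without the mutant-fragment library of 24 h the list's direction turned (adjusted p = 0.547). Idi1 (-1.29), Pmvk (-1.16) and Insig1 (-0.94) were among the largest changes.

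Complement and phagocytic receptors, and cell cycle genes, passed in camera with directions that rest on 1 time. The 19 complement and phagocytic receptor genes (median 0.17, mean 0.66, camera adjusted p = 0.00963, adjusted p = 0.703 with an estimated correlation) had a median difference of -0.41 at 24 h and 0.72 at the second time. Marco, C3 (2.76), C3ar1 (1.25) and Msr1 (1.11) were their largest changes, and 5 passed adjusted over the list alone, 4 of them higher. Without the mutant-fragment library of the second time this list's direction turned (adjusted p = 0.659). The 27 cell cycle genes (median 0.30, camera adjusted p = 0.0394, adjusted p = 0.772 with an estimated correlation) had a median of 0.64 at 24 h and -0.04 at the second time, 0 passed adjusted over the list alone in limma (Mki67 -0.93, Aurka 0.73, Mcm2 0.65, Rrm2 0.64), and the direction turned without the mutant-fragment library of 24 h (adjusted p = 0.523). After quantile normalization the cell cycle list was not called (adjusted p = 0.0984). With fry 0 lists passed, the lowest adjusted p being 0.0681.

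**Figure D3:**
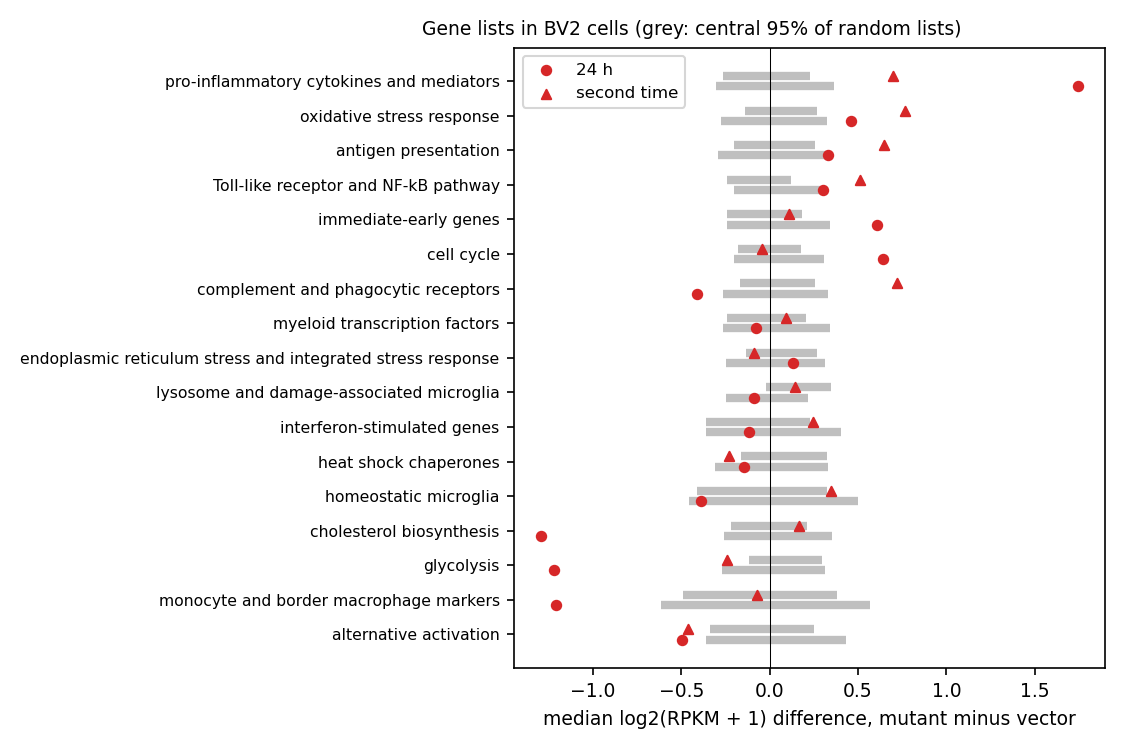
Median log2(RPKM + 1) difference between mutant-fragment and empty-vector cells for each gene list at 24 h (circles) and the second time (triangles), with the central 95% of matched random lists in grey. Pro-inflammatory genes lie to the right of the grey range at both times (1.74 and 0.70), and cholesterol biosynthesis lies to its left at 24 h alone (-1.29).

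The other 9 lists tested were not called in this comparison. Alternative activation genes (11 tested) had a median of -0.64 (camera adjusted p = 0.0884), with Arg1, Clec10a (-2.19) and Chil3 (-1.71) low and Il1rn (2.08), the interleukin-1 receptor antagonist, high. Immediate-early genes (19, median 0.40, adjusted p = 0.142) included Dusp1 (2.05), Atf3 (1.35) and Jund (1.25) on 1 side and Nr4a1 (-1.59) on the other. Myeloid transcription factors (17, median 0.06, adjusted p = 0.788) split between Ets2 (2.71), Cebpd (2.30) and Spi1 above and Mef2c (-1.64) below. Lysosome and damage-associated genes (22, median -0.01, adjusted p = 0.202) held Lyz2 (1.21), Lgals3 (1.13) and Ctsd (1.02) against Cst7 (-1.39). Heat shock chaperones (15, median -0.20, adjusted p = 0.0957, or 0.0201 after quantile normalization), monocyte and border macrophage markers (5, -0.64, 0.117), interferon-stimulated genes (10, -0.05, 0.788), endoplasmic reticulum stress genes (20, 0.03, 0.788) and homeostatic microglia genes (7, median -0.20, mean 0.02, 0.985) were not called either. Adjusted over the list alone, 6 immediate-early, 6 lysosome, 5 transcription factor, 2 alternative activation, 2 endoplasmic reticulum stress and 1 monocyte gene passed. Markers of other cells were scarce: 3 granulocyte genes (median 0.80, with Lcn2 at 0.106 and 0.084 RPKM with the empty vector and 219 and 1.98 RPKM with the mutant fragment), 2 astrocyte genes (0.15), and 1 each for endothelial cells (-1.43), lymphocytes (0.70), neurons (0.20) and oligodendrocytes (-0.61) were tested, and 0 for fibroblasts and the kynurenine pathway.

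The wild-type fragment gave no call against the empty vector. No gene passed in either direction (limma, 0 higher and 0 lower, 66 genes with an unadjusted p under 0.05). Of transcripts of 200 bases or more, 0 were at least 2-fold higher or lower at both times, and at 24 h alone 1 was higher and 1 lower. The genes named by size were all short RNAs, among them Mir7023 (2.76), Mir6980 (2.27), Mir1231 (2.13), Mir6959 (-2.81) and Mir7652 (-2.30). Between the 2 times the differences of genes of 200 bases or more had a Pearson r of 0.026 and a Spearman rho of 0.037 across genes. No list passed (lowest camera adjusted p = 0.204), and 3 to 7 lists passed when single libraries were left out. Without the wild-type-fragment library of 24 h, 31 genes were higher and 11 lower, and 3 and 10 without that of the second time.

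Set against the wild-type fragment, the mutant fragment raised 7 genes: Pilrb1 (3.73), Il1a (3.43), Pilrb2 (3.32), Ebi3 (3.23), Clec4n (2.75), Clec4a1 (2.74) and Nfkbia (2.36), each with an SE between 0.16 and 0.18 (limma, adjusted p between 0.0271 and 0.0434). Marco (4.91) and Pilra (2.70) had an adjusted p of 0.0526. No gene passed as lower, and 1644 had an unadjusted p under 0.05. By size, the lower genes were Arg1 (-4.25), Ankrd37 (-3.55), Bnip3 (-3.04), Abcd2 (-2.94), Atp6v0d2 (-2.87), Selenbp1 (-2.85), F13a1 (-2.57) and Tmem26 (-2.23), with 4 micro-RNA entries (Mir6987, Mir7077, Mir7083 and Mir6921). In this comparison 8 lists passed in camera, led by pro-inflammatory genes (median 1.04, adjusted p = 2.00e-09, adjusted p = 0.363 with an estimated correlation; 9 of 15 adjusted over the list alone, all higher). The others were antigen presentation and oxidative stress (6.20e-05 each), glycolysis (1.25e-04), Toll-like receptor genes (0.00139), cell cycle (0.00763), and complement and cholesterol genes (0.0189 each), and with an estimated correlation the lowest adjusted p over all lists was 0.357. Only the pro-inflammatory and oxidative stress lists kept their call without any 1 library. Without the mutant-fragment library of 24 h calls ended for glycolysis (adjusted p = 0.348) and cell cycle genes (0.977) and the direction turned for cholesterol genes (0.221). Without that of the second time calls ended for Toll-like receptor (0.111) and antigen presentation genes (0.0636) and the direction turned for complement genes (0.623). Without the wild-type-fragment library of 24 h calls ended for cell cycle (0.233) and cholesterol genes (0.141). This comparison uses the same mutant-fragment libraries as the one with the empty vector, so the 2 are not independent. The count was 0 with a pseudocount of 5 or no filter on low values, and 4 without the time term. It was 46 higher and 19 lower without either empty-vector library, 50 and 27 or 86 and 51 without the wild-type-fragment library of 24 h or the second time, and 556 and 1149 or 1741 and 1574 without that of the mutant fragment.

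Time was the other factor in BV2 cells, where the 3 constructs take the place of replicates. If libraries of the same time shared a harvest, time cannot be told apart from harvest. At the second time, genes of mitosis and DNA synthesis were higher in all 3 constructs: Kif20a, a mitotic kinesin, was at 3.05 RPKM at 24 h and 16.8 RPKM at the second time with the empty vector, at 2.60 and 15.9 with the wild-type fragment and at 3.21 and 17.5 with the mutant fragment. Rrm2 (2.28), Tubb4b (2.23), Plk1 (2.15) and Mybl2 (2.05) were likewise named by size. Lower by size were Ddit3 (-2.78), Cox6a2 (-2.15), Txnip (-2.02), Phyhd1 (-1.75) and Mir5107 (-1.94). In limma 0 genes passed either way, with adjusted p = 0.0560 for most of these and 2812 genes at an unadjusted p under 0.05. At least 2-fold in all 3 constructs were 91 higher and 19 lower genes. All 27 cell cycle genes passed, higher, adjusted over the list alone (median 1.58, camera adjusted p = 6.56e-16), as did 11 of 18 cholesterol genes (median 0.98, 8.51e-06) and 3 heat shock genes (0.41, 0.00410). Antigen presentation (-0.47), lysosome (-0.27), immediate-early (-0.27), alternative activation (-0.55), monocyte (-0.99) and interferon (-0.32) genes were lower in camera (adjusted p between 8.51e-06 and 0.00769), and with an estimated correlation the lowest adjusted p of any list was 0.444. Without transcripts under 200 bases, a setting chosen after the data were seen, 456 genes were higher and 87 lower. They were 81 and 43 without either wild-type-fragment library and 3060 and 1412 without either mutant-fragment library.

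In the chromatin of the same cells, peak sets of H3K4me2 were similar in number across constructs while those of the C/EBP factors were not. H3K4me2 had 39503, 39445 and 42514 peaks with the empty vector, the wild-type and the mutant fragment, and PU.1 71846, 53835 and 64744. C/EBPα had 11645, 19732 and 9117 peaks, and C/EBPβ 35964, 69522 and 47893. The share of tags in peaks, given by the authors in the headers, was 8.09%, 23.02% and 24.31% for C/EBPβ and 2.38%, 4.10% and 3.88% for C/EBPα, so libraries differ in enrichment as well as depth. Tags per bp in the headers were 0.00345, 0.00401 and 0.00116 for C/EBPα and 0.00522, 0.00400 and 0.00165 for C/EBPβ, lowest with the mutant fragment. Total tags differed less, at 16.3, 24.1 and 14.7 M for C/EBPα and 17.5, 17.7 and 13.6 M for C/EBPβ. With 1 library per antibody and construct, no difference in number has a replicate check.

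Of H3K4me2 peaks in mutant-fragment cells, 82.8% (95% interval 82.4 to 83.1) overlapped one in empty-vector cells, against 89.2% (88.9 to 89.5) of wild-type-fragment peaks. For PU.1 these shares were 75.4% (75.0 to 75.7) and 81.9% (81.6 to 82.2), for C/EBPα 68.7% (67.7 to 69.6) and 47.6% (46.9 to 48.3), and for C/EBPβ 59.1% (58.7 to 59.6) and 45.5% (45.2 to 45.9). The larger C/EBPα and C/EBPβ lists of wild-type-fragment cells held 80.6% and 88.0% of the empty-vector peaks and 83.0% and 84.5% of the mutant-fragment peaks. Shifted peaks overlapped in 12.7% to 14.1% for H3K4me2 and 0.326% to 2.19% for the factors. The factors also lay together: 92.0%, 91.0% and 94.9% of C/EBPα peaks (empty vector, wild-type and mutant fragment) overlapped a C/EBPβ peak of the same cells, against 1.24% to 2.02% of shifted peaks. Of C/EBPβ peaks, 22.0%, 16.6% and 22.7% overlapped PU.1 and 49.9%, 42.2% and 51.6% overlapped H3K4me2, and of PU.1 peaks 37.1%, 38.4% and 39.6% overlapped H3K4me2.

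Around the raised genes, Pilrb1 had 0 H3K4me2 peaks within 20 kb of its start in empty-vector and in wild-type-fragment cells and 3 in mutant-fragment cells, at 138297585 to 138298613, 138299722 to 138300502 and 138311324 to 138312971 on chromosome 5. Pilrb2 had 2, 2 and 5 such peaks, the 3 further ones being those of Pilrb1. Marco had 3, 5 and 6, Clec4a1 1, 1 and 3, Clec4n 1, 0 and 2, Ebi3 3, 3 and 4, Nfkbia 5, 4 and 5, and Il1a 7, 6 and 6. Pilra had 4, 4 and 3, where 1 mutant-fragment peak spans 2 of the empty vector. Of the 9 raised genes, 7 had a C/EBPα peak of mutant-fragment cells within 20 kb, against 32.4% of other genes (Fisher's exact test, two-sided, p = 0.00694, adjusted p = 0.0555 over 8 tests). None of these 8 tests, of 4 antibodies in mutant-fragment and empty-vector cells, passed. For H3K4me2, PU.1 and C/EBPβ of mutant-fragment cells, 9, 9 and 8 of the 9 genes had a peak, and 96.3%, 87.7% and 83.1% of other genes. In a wider set chosen after the data were seen, the 89 genes at least 2-fold higher at both times, 63 (70.8%) had a C/EBPα peak of mutant-fragment cells against 32.2% of other genes (adjusted p = 2.57e-12 over 16 tests), and 59 (66.3%) had one of empty-vector cells against 38.3% (adjusted p = 1.06e-06). Peaks were also more frequent near these genes for PU.1 of mutant-fragment cells (89 of 89 against 87.8%, adjusted p = 1.13e-04) and C/EBPβ of empty-vector cells (88.8% against 73.7%, adjusted p = 0.00371), so this is not particular to C/EBPα. Neighbours that share peaks, such as Pilrb1 and Pilrb2, count as separate genes in this wider set, so its p-values may be too low. The other genes in these tests were not matched on expression level.

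**Figure D4:**
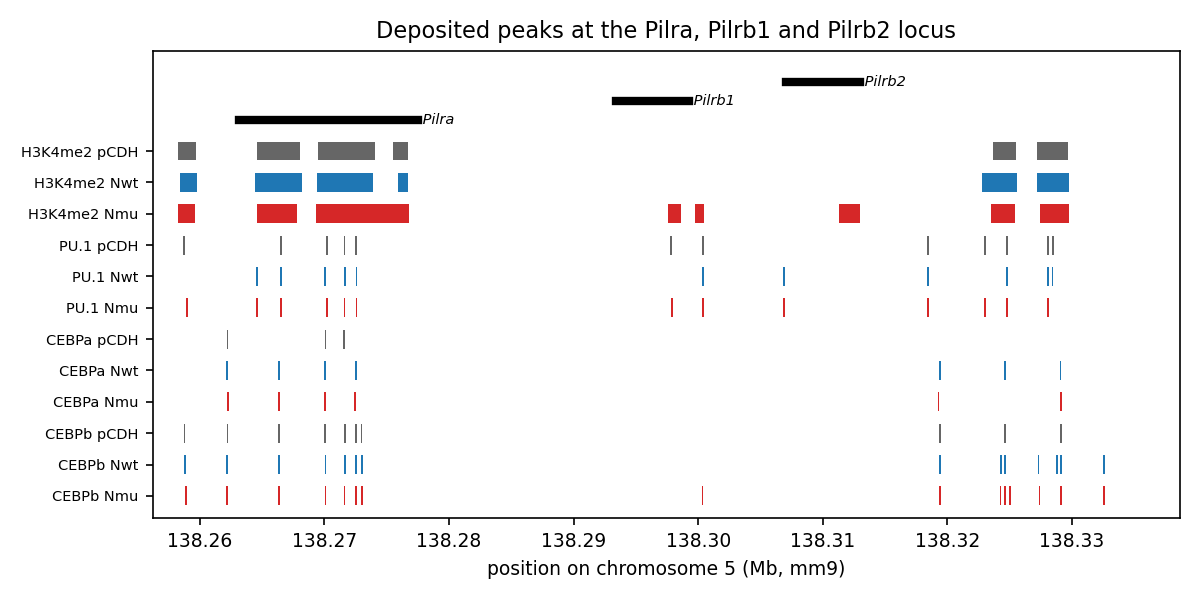
Peaks of the 12 ChIP-seq libraries (rows, one per antibody and construct) along chromosome 5 of mm9 around Pilra, Pilrb1 and Pilrb2 (black bars). In the row of H3K4me2 with the mutant fragment, 3 peaks lie at and between Pilrb1 and Pilrb2 (138297585 to 138312971) where the empty-vector and wild-type-fragment rows have none.

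Over both primary cell types, the genes called lower with mutant huntingtin included some, but not all, of those of neutrophil granules. S100a9, a calcium-binding protein abundant in granulocytes, was at 692 RPKM in wild-type and 217 RPKM in mutant microglia, and at 243 and 108 RPKM in macrophages (log2 fold change -1.41 over both cell types, SE 0.26, adjusted p = 1.41e-04 in limma). S100a8 (-1.29), Chil3 (-1.35), Ltf (-1.17), Pglyrp1 (-1.08), Cd177 (-1.07), Lcn2 (-1.04) and Camp (-1.01) were also called lower, as were C3, the central complement component (-1.21), Cybb, the catalytic subunit of the phagocyte oxidase (-1.03), Saa3 (-1.01) and 1100001G20Rik (-0.99). The granulocyte markers Retnlg, Elane, Prtn3 and Mpo were lower in mutant microglia but higher in mutant macrophages, and were not called. Ngp and Csf3r were not called either, and no list was tested over both cell types. Because all genes share 1 SE, a change mainly in 1 cell type can be called too. Camp was at -1.60 in microglia and -0.43 in macrophages, while Lcn2 was at -1.09 and -0.98. Over the other settings, some of which rest on 1 cell type, Saa3 lay between -1.83 and -0.18. Of genes of 200 bases or more, only 1 was at least 2-fold lower in both cell types. Called higher were Abhd1 (1.34) and the histone gene Hist1h2bl (1.16). In all 12 genes were called higher and 24 lower among 10687, of which 10 and 12 were transcripts under 200 bases, and 283 genes had an unadjusted p under 0.05. No call was left after quantile normalization, with a pseudocount of 5, with no filter on low values or in 1 fit of all 10 RNA libraries. With any 1 of the 4 libraries left out, the genotype difference rests on 1 cell type and the error on BV2 cells. Such fits therefore cannot test these calls. Huntingtin itself was at 3.40 and 2.72 RPKM in wild-type and mutant microglia and 4.22 and 1.26 RPKM in macrophages (-0.72, adjusted p = 0.666).

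Of the 11 granulocyte markers 4 were higher in mutant macrophages and 1 was at least 2-fold lower there. Within microglia, the granulocyte markers had the lowest median of all lists, -1.27 for 11 genes, below all 10000 matched random lists, and 8 of the 11 were at least 2-fold lower. Camp was at 124 RPKM in wild-type and 40.2 RPKM in mutant cells, and Ngp was at 74.2 and 30.3 RPKM, while Csf3r, the receptor for granulocyte colony-stimulating factor, was at 42.5 and 45.7 RPKM. The sort for CD45-low cells is meant to leave out granulocytes, which are CD45-high, but how complete it was is not known. The list of monocyte and border macrophage markers had a median of -0.89 (9 genes, percentile 0), with 3 at least 2-fold lower, Plac8 (-1.57) and Ly6c2 (-1.32) among them, and 3 higher, Mrc1, Pf4 and Ms4a7, each at 2.05 RPKM or less. The largest single differences on the lower side were Chil3 (-1.76, from 67.4 to 19.1 RPKM), S100a8 (-1.69), S100a9 (-1.67), Ltf (-1.65), Camp (-1.60), Plac8, Retnlg (-1.53), S100a6 (-1.51) and Hp (-1.51), and the micro-RNA entry Mir6904.

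Among genes higher in mutant microglia were Apoe, a lipid carrier raised in damage-associated microglia (187 to 479 RPKM, 1.36), Egr3, an immediate-early factor (8.99 to 22.7 RPKM, 1.24), Vmp1 (1.24) and its neighbour Mir21 (1.21), and the interferon-responsive genes Ifi204 (1.13), Ifi27l2a (1.11) and Ifit3 (1.06). Also higher were 3 micro-RNA entries (Mir6928, Mir6954 and Mir7001). As a list, 25 of 29 interferon-stimulated genes were higher (median 0.40, above all 10000 random lists), with Oasl2 (1.02), Usp18 (0.74) and Oas1a (0.73) beside Ifit3. Pro-inflammatory genes (17, median 0.15, percentile 100) held Ccl3 at 212 and 306 RPKM and Tnf at 25.9 and 40.1 RPKM, with Csf1 (0.70) above and Cxcl2 (-0.77) below. Immediate-early genes (0.08, percentile 99.965), lysosome and damage-associated genes (0.03, 99.57), Toll-like receptor genes (0.00, 99.14) and myeloid transcription factors (0.02, 99.06) also lay above the central 95% of random lists, whose median is below 0 because the median gene was at -0.08.

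Lower in mutant microglia than in matched lists were cell cycle genes (median -0.29, 1 of 27 higher), heat shock chaperones (-0.33, percentile 0.02, with Hspa1b at -0.87 and Hspa1a at -0.69, near-identical genes), endoplasmic reticulum stress genes (-0.26, 1.25, with Sdf2l1 at -0.83) and oxidative stress genes (-0.21, 2.37, or 2.84 after quantile normalization, with Cybb at -0.95 and Hmox1 at 0.73). Homeostatic microglia genes (median -0.23, percentile 11.9) lay within the range, with 2 of 18 higher, Cx3cr1 at 464 and 332 RPKM and Fcrls at -0.55. So did antigen presentation (-0.08, percentile 70.4, with B2m at 391 and 604 RPKM), alternative activation (-0.10, 36.8), cholesterol biosynthesis (-0.10, 19.0), complement and phagocytic receptors (-0.11, 60.2, with Axl at 3.09 and 7.36 RPKM) and glycolysis (-0.19, 5.48, or 0.970 with a pseudocount of 5). At least 2-fold were 19 higher and 54 lower genes, or 9 and 32 of 200 bases or more. After quantile normalization the medians of antigen presentation and complement genes turned positive.

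In macrophages, 5 lists had a median genotype difference below matched random lists and 1 a median above them. Lars2, a mitochondrial leucyl-tRNA synthetase, was at 64.6 and 9.30 RPKM in wild-type and mutant cells (-2.67), Saa3 at -1.83, C3 at 41.5 and 13.5 RPKM (-1.55), Vegfa at 84.6 and 30.6 RPKM (-1.44) and Thbs1 at -1.42, with 5 micro-RNA entries beside them. Lars2 was also the gene with the most reads in every BV2 library, so what its reads stand for is uncertain. Higher were the histone genes Hist1h4j (1.57) and Hist1h4k (1.50), the small nucleolar RNAs Snora5c (1.51) and Snora41 (1.39), and 6 micro-RNA entries. The median gene was 0.18 higher in the mutant library, so lists are read against matched random lists. Below their range lay granulocyte markers (-0.43, percentile 0.01), immediate-early genes (-0.18, 0.02, with Fosb at 3.86 and 0.672 RPKM and Btg2 at 26.1 and 11.6 RPKM), antigen presentation (-0.10, 0.77, 9 of 20 higher, with the class II genes H2-Eb1 at -1.13 and Cd74 at 172 and 81.6 RPKM), Toll-like receptor genes (0.01, 1.26, 15 of 28 higher) and pro-inflammatory genes (-0.04, 1.84, or 7.51 after quantile normalization, 6 of 17 higher, with Il1b at -1.06 and Ccl4 at 0.77). Above it lay cholesterol biosynthesis (0.39, percentile 98.6, or 96.7 after quantile normalization, 16 of 18 higher, with Nsdhl at 0.77 and Fdps at 0.73).

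Inside the range in macrophages were oxidative stress (0.35, percentile 96.9, with Cybb at 609 and 280 RPKM) and lysosome genes (0.31, 95.7), both above it without transcripts under 200 bases (98.00 and 98.09), and cell cycle (0.28, 89.5, with Pcna at 101 and 189 RPKM), myeloid transcription factors (0.26, 82.3, with Spi1 at 23.4 and 45.0 RPKM), complement (0.24, 82.6), endoplasmic reticulum stress (0.22, 78.3), monocyte (0.16, 64.8), glycolysis (0.14, 37.9), interferon (0.09, 19.1), heat shock (0.05, 22.5), homeostatic (0.02, 12.3) and alternative activation genes (-0.04, 4.20). At least 2-fold were 140 higher and 68 lower genes, or 70 and 105 after quantile normalization, so the side with more genes depends on the scaling. Quantile normalization also turned the medians of Toll-like receptor, glycolysis, heat shock, homeostatic and interferon genes below 0. Of genes of 200 bases or more, 0 were at least 2-fold higher and 1 lower in mutant cells of both types.

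**Figure D5:**
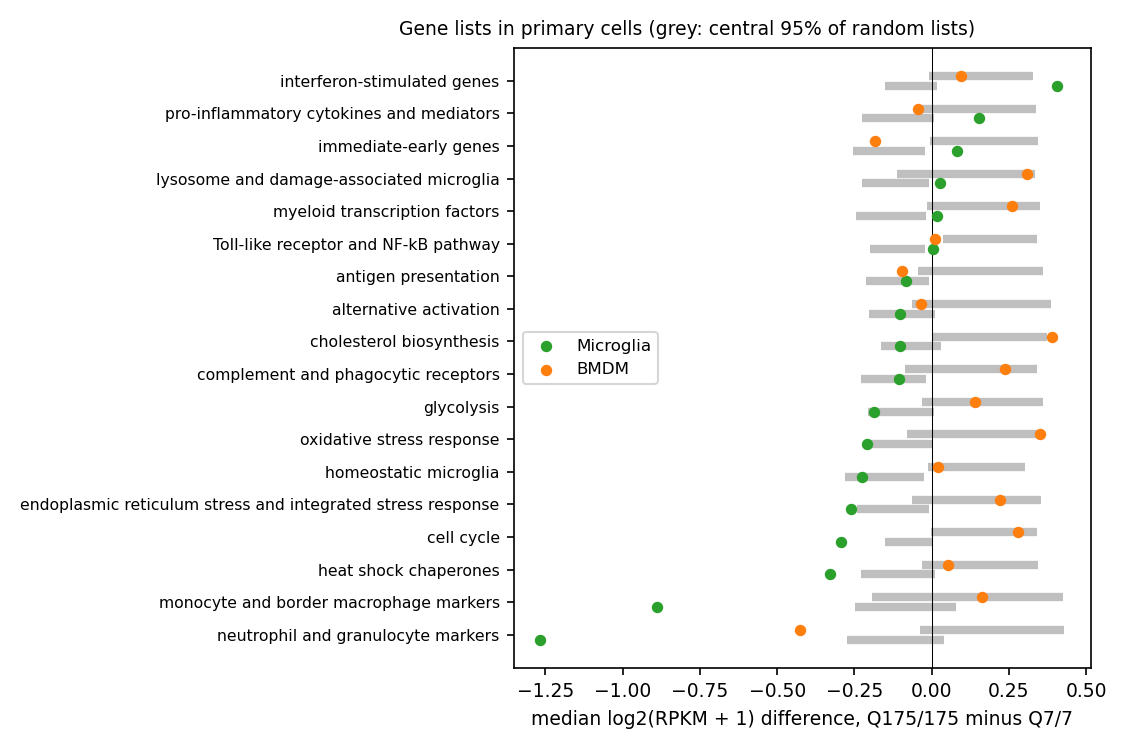
Median log2(RPKM + 1) difference between mutant (Q175/175) and wild-type (Q7/7) libraries for each list in microglia (green) and bone marrow derived macrophages (BMDM, orange), 1 library per genotype, with the central 95% of matched random lists in grey. Granulocyte markers lie to the left of the grey range in both (-1.27 and -0.43), and interferon-stimulated genes to its right in microglia (0.40).

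Genes raised by the mutant fragment in BV2 cells were then examined in the primary cells. Of the 9, 7 were expressed there, with a median genotype difference of -0.01 in microglia (percentile 80.8 among matched random lists) and -0.16 in macrophages (percentile 1.31), and 3 of the 7 were higher in each. Of the 89 genes at least 2-fold higher at both times, a set chosen after the data were seen, 76 were expressed. Their median was -0.03 in microglia (percentile 99.51) and 0.01 in macrophages (percentile 0). With transcripts under 200 bases included (122 genes, 87 expressed) it was -0.07 in microglia (percentile 84.2), inside the central 95%, and 0.01 in macrophages (percentile 0). The 39 expressed genes of the 59 lower ones had medians of -0.06 (percentile 78.3) and 0.13 (percentile 14.2).

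The last comparison is between the primary cell types, whatever the genotype. Microglia had the genes that mark their homeostatic state, such as Tmem119 at 334 and 288 RPKM (wild-type and mutant) against 0.701 and 0.232 RPKM in macrophages, P2ry12, a purinergic receptor (log2 fold change 7.44), Siglech (7.26), Gpr34 (6.86), Olfml3 (6.61) and Cx3cr1, the fractalkine receptor (6.38). Sparc (7.51) and the small nucleolar RNAs Snora81 (7.04), Snora65 (6.46) and Snora30 (6.34) were also among the 10 highest. Macrophages had Gpnmb at 1052 and 1283 RPKM against 1.37 and 0.762 RPKM in microglia (-9.15), Lgals3 (galectin-3, -8.57), Cd5l (-8.19), the fatty acid transporter Cd36 (-8.13), the lipase Lpl (-7.80), Vim (-7.48), Spp1 (osteopontin, -6.94), S100a4 (-6.86), Lgals1 (-6.74) and Clec4d (-6.50). With an SE of 0.26 in limma, 1940 genes were higher and 5255 lower in microglia among 10687, of which 293 and 71 were transcripts under 200 bases. Rmrp, a noncoding RNA named outside the rule, had the most reads in both microglia libraries, and Lyz2 in both macrophage libraries. Whether short RNAs differ by cell type or by the make-up of the libraries was not tested. Microglia were sorted from brain and macrophages grown in culture. Here and in the lists below, cell type therefore cannot be told apart from the way the cells were prepared. The median gene was at -0.53, and after quantile normalization, which removes that shift, the split was 3528 and 3498. Without either wild-type library it was 1199 and 3973, and without either mutant library 1551 and 3051. Cebpa (2.65, adjusted p = 1.2e-22) and Irf8 (1.28, adjusted p = 3.6e-06) were higher in microglia, while Cebpb (0.47, adjusted p = 0.100), Spi1 (-0.07, adjusted p = 0.832) and Htt (0.24, adjusted p = 0.430) did not differ past the threshold.

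In the lists, genes were counted in the same test against 0, with the shift of the median gene not removed, while list medians are given relative to it. Of the homeostatic microglia genes, 17 of 18 passed as higher in microglia (list median 5.92) and 20 of 21 immediate-early genes did (3.35). All 27 cell cycle genes (-2.80), 27 of 29 interferon-stimulated genes (-1.95), 18 of 18 cholesterol genes (-1.38) and 16 of 18 oxidative stress genes (-1.67) passed as lower. Granulocyte markers passed as higher in 8 of 11 genes (2.30) and as lower in 0, and monocyte markers as higher in 1 and lower in 7 of 9. In the other lists the genes passing as higher and lower were 3 and 15 of 20 for antigen presentation, 1 and 16 of 22 for lysosome, 10 and 1 of 19 for myeloid transcription factors, 9 and 8 of 28 for Toll-like receptor genes and 3 and 6 of 12 for alternative activation. They were 8 and 11 of 22 for complement, 7 and 10 of 19 for endoplasmic reticulum stress, 2 and 13 of 18 for glycolysis, 6 and 6 of 16 for heat shock and 8 and 8 of 17 for pro-inflammatory genes. Few markers of other cells were expressed: astrocyte (1 higher and 2 lower of 3), oligodendrocyte (1 and 1 of 3), endothelial (1 and 1 of 2) and lymphocyte genes (1 and 0 of 1). Of 2 kynurenine pathway genes expressed, 1 was higher and 0 lower.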

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

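No explanation was tested for the results in this part, and the size limits used to pick them out were chosen after the data had been seen. In the primary cells each genotype has 1 library per cell type, so none of the differences between microglia and macrophages was tested.

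For 3 gene lists the median genotype difference lay above matched random lists in 1 primary cell type and below them in the other, although the medians themselves were small. Immediate-early genes had a median difference above matched random lists in microglia (percentile 99.965) and below them in macrophages (percentile 0.02). Their medians were 0.08 and -0.18, or 0.18 and -0.35 after quantile normalization. Toll-like receptor and NF-kB pathway genes lay at percentile 99.14 in microglia and 1.26 in macrophages, with medians near 0 in both (0.00 and 0.01), or 0.10 and -0.14 after quantile normalization. Pro-inflammatory cytokines and mediators lay at percentile 100 in microglia and 1.835 in macrophages, and after quantile normalization the latter became 7.51, inside the central 95%.

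Single named genes did so too, each by at least 0.5 on the log2(RPKM + 1) scale in both cell types. Apoe was 1.36 higher in mutant microglia, and its difference in macrophages was -1.11 (322 and 149 RPKM in wild-type and mutant). Lars2, whose reads are of uncertain source as given above, had differences of 0.77 in microglia, where it was at 1.16 and 2.67 RPKM, and -2.67 in macrophages. For the interferon-stimulated gene Ifit3 they were 1.06 and -0.55, with 35.3 and 23.8 RPKM in wild-type and mutant macrophages. Plac8 had -1.57 in microglia and 1.01 in macrophages (8.54 and 18.2 RPKM), and the histone gene Hist1h4k -0.56 and 1.50.

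In BV2 cells the effect of the mutant fragment differed between the 2 times in some genes, again with no test of the difference, since each construct has 1 library per time. Complement and phagocytic receptor genes had a median difference at percentile 0.23 of matched random lists at 24 h and at percentile 100 at the second time. At least 2-fold opposite ways at the 2 times were 11 genes of 200 bases or more, named here outside the rule and after their values were seen. Lower at 24 h and higher at the second time were S100a11 (-1.98 and 1.02), Glrx (-1.38 and 1.47) and Cyb5 (-1.20 and 1.13). Higher at 24 h and lower at the second time were Ncl, the gene of nucleolin (1.20 and -1.34), Mphosph10 (1.02 and -1.09), the histone genes Hist1h3a, Hist1h3b, Hist1h3c and Hist1h3i, and the entries BB287469 and Gm4027.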

How the results depend on the processing

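The settings without transcripts under 200 bases, with genes at least 2-fold changed at both times, with 1 gene per 100 kb, with shifted peaks and with peaks of 1 construct alone were chosen only after the data had been seen. The edgeR test on recovered reads was not run, though the lowest values were whole multiples of 1 read. The comparison of top-scored peaks was not run either, because every deposited score is 1. The fit of BV2 cells is blocked by time, and without that term 3 genes instead of 9 passed against the vector. The fit of the primary cells is blocked by cell type. Within a cell type no test was possible, because each group there has 1 library. Where a library was left out, the arm with 1 library was assumed to vary like the other groups, and primary libraries were left out of a fit of the remaining 9 RNA libraries. In that fit the error came from BV2 cells alone. Depth (10.8 to 14.0 M reads in BV2 cells, of which 3.63 to 4.71 M on gene transcripts) limits genes of low RPKM and short transcripts. There a few reads make a large fold.

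Calls for the mutant fragment against the empty vector, 9 higher and 0 lower, became 17 and 4 with a pseudocount of 0.1, 0 higher with a pseudocount of 5 or no filter, 18 and 1 with an RPKM of 5 or more, 77 and 44 in 1 fit of all 10 RNA libraries, 37 and 2 with every transcript, 3 higher with no time term and 24 and 3 without transcripts under 200 bases. The 9 genes were all called with an RPKM of 5 or more, in the fit of all 10 libraries and without short transcripts, and 8 of them, without Marco, with a pseudocount of 0.1 and after quantile normalization. Called without the empty-vector library of 24 h were 7 of them, without Clec4a1 and Nfkbia, and without that of the second time 5, without Pilra and Clec4n as well. Left-out libraries gave 5 to 1764 higher and 0 to 1526 lower. The ends come from the empty-vector library of the second time (5 and 0) and the mutant-fragment library of the second time (1764 and 1526). The mutant-fragment library of 24 h gave 521 and 929, either wild-type-fragment library 129 and 100, and the empty-vector library of 24 h 13 and 3. Without 1 mutant-fragment library the fit no longer counts the difference between its times as error, by construction. For the wild-type fragment (0 and 0) left-out libraries gave 0 to 31 higher and 0 to 11 lower, with 31 and 11 without its library of 24 h and 3 and 10 without that of the second time.

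For the mutant against the wild-type fragment, 7 higher and 0 lower became 17 and 2 (pseudocount 0.1), 0 higher (pseudocount 5, no filter), 17 and 1 (RPKM of 5 or more), 77 and 56 (all 10 libraries), 29 and 1 (every transcript), 4 higher (no time term) and 24 and 2 (no short transcripts). Left-out libraries gave 46 to 1741 higher and 19 to 1574 lower. These were 46 and 19 for either empty-vector library, 50 and 27 or 86 and 51 for the wild-type-fragment library of 24 h or the second time, and 556 and 1149 or 1741 and 1574 for that of the mutant fragment. For time, 0 and 0 became 363 and 81 (pseudocount 5), 106 and 18 (RPKM of 5 or more), 634 and 178 (all 10 libraries), 24 and 6 (every transcript) and 456 and 87 (no short transcripts). Left-out libraries gave 0 to 3060 higher and 0 to 1412 lower, with 81 and 43 without either wild-type-fragment library and 3060 and 1412 without either mutant-fragment library. Beyond what the constructions show, the cause was not tested.

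Of the lists, 8 (mutant fragment against vector), 8 (against the wild-type fragment) and 9 (time) passed in camera, and 0 of each with an estimated correlation and with fry. Left-out libraries gave 7 to 10, 6 to 10 and 9 to 13, and 3 to 7 for the wild-type fragment, where 0 passed with all libraries. Directions turned against the vector for cell cycle (adjusted p = 0.523) and cholesterol genes (0.547) without the mutant-fragment library of 24 h, and for complement genes (0.659) without that of the second time, these being the highest values over left-out libraries. The lowest were 1.68e-04, 9.18e-08 and 4.93e-08 in the same order. Against the wild-type fragment directions turned for cholesterol (0.221) and complement genes (0.623) without the same libraries, where the lowest values were 3.35e-06 and 3.75e-06. Calls ended without the mutant-fragment library of 24 h for glycolysis (0.229 against the vector, 0.348 against the wild-type fragment) and cell cycle genes (0.977 against the wild-type fragment), and without that of the second time for Toll-like receptor (0.0929 and 0.111) and antigen presentation genes (0.0636 against the wild-type fragment). They also ended against the vector without its library of 24 h for cell cycle (0.413) and cholesterol genes (0.276) and without that of the second time for complement genes (0.251). Without the wild-type-fragment library of 24 h they ended for cell cycle (0.233) and cholesterol genes (0.141) against that fragment, and without either of its libraries for interferon genes with time (0.0534). Pro-inflammatory and oxidative stress genes kept their call for the mutant fragment without any 1 library. The cause was not tested.

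Between mutant and wild-type primary cells, 12 higher and 24 lower became 69 and 41 with a pseudocount of 0.1, 1 and 5 with an RPKM of 5 or more, and 2 and 12 without short transcripts. With a pseudocount of 5, no filter, quantile normalization and 1 fit of all 10 libraries there were 0 and 0, and with an intensity trend 21 were higher. Left-out libraries cannot test these calls, because the genotype difference then rests on 1 cell type. Between microglia and macrophages, 1940 higher and 5255 lower became 3528 and 3498 after quantile normalization, and 1077 were higher with an RPKM of 5 or more, where fewer genes were tested. Left-out libraries gave 1199 to 1551 higher and 3051 to 3973 lower, with 1199 and 3973 without either wild-type library and 1551 and 3051 without either mutant library. Within microglia, 19 genes at least 2-fold higher and 54 lower became 57 and 210 with a pseudocount of 0.1, 4 and 12 with 5, and 9 and 32 without short transcripts, and 32 were higher after quantile normalization. In macrophages, 140 and 68 became 385 and 118, 14 and 20, 71 and 36, and 70 and 105 in the same order. A smaller pseudocount enlarges folds of low values, and short transcripts are low in reads. List medians moved with it too: in microglia that of cell cycle genes (-0.29) was -0.58 with a pseudocount of 0.1 and -0.08 with 5. That of interferon genes (0.40) was 0.54 and 0.19. The number of lists outside the central 95% (12 in microglia, 6 in macrophages) stayed within 1.5 times under each setting, though after quantile normalization pro-inflammatory (7.51) and cholesterol genes (96.7) of macrophages and oxidative stress genes of microglia (2.84, and 2.62 with a pseudocount of 0.1) lay inside. Outside, by contrast, lay oxidative stress (98.00) and lysosome genes (98.09) of macrophages without short transcripts, oxidative stress genes there with a pseudocount of 0.1 (98.04), and glycolysis genes of microglia with a pseudocount of 5 (0.970). The raised BV2 genes lay at percentile 80.8 in microglia, and at 99.51 as the 2-fold set of 200 bases or more.

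With an overlap of at least 0.5 of the shorter peak, the shares of wild-type-fragment peaks in the empty vector, of mutant-fragment peaks in the empty vector and of mutant-fragment in wild-type-fragment peaks were 88.2%, 82.0% and 80.4% for H3K4me2, 80.9%, 74.5% and 63.5% for PU.1, 45.2%, 64.5% and 78.4% for C/EBPα and 44.2%, 56.9% and 80.9% for C/EBPβ. Shares with another antibody (empty vector, wild-type and mutant fragment) were 89.1%, 87.4% and 89.9% for C/EBPα in C/EBPβ, 15.8%, 12.0% and 16.8% for C/EBPβ in PU.1, 48.3%, 40.5% and 49.5% for C/EBPβ in H3K4me2 and 35.9%, 36.9% and 38.3% for PU.1 in H3K4me2. A stricter overlap lowers every share by construction. Of the tests of peaks near raised genes, 0 passed, against 1 with a 50 kb window, 2 with peaks of 1 construct alone and 4 with the 2-fold set of 200 bases or more, all with more peaks near raised genes. In the 2-fold set with short transcripts (122 genes) 4 passed, of which 2 had fewer H3K4me2 peaks near raised genes (86.9% against 96.2% with the empty vector, 88.5% against 96.4% with the mutant fragment).

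Over named genes, the BV2 lists called in camera and the percentiles of the primary lists, 921 values kept direction and side of the threshold or range, 57 gained a call, 239 lost one, 8 percentiles crossed the range and 5 BV2 lists turned, as given above. Medians of primary lists that changed sign after quantile normalization are not among these counts, nor are BV2 lists that gained a call, such as heat shock chaperones after quantile normalization (0.0201 against the vector, 0.0225 against the wild-type fragment). Of counts and shares, 126 stayed within 1.5 times or their interval and 156 moved.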

Other observations

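The tests of explanations in the last 3 paragraphs were chosen only after the results they measure had been seen.

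Single genes of BV2 cells with the mutant fragment are given here from lists that were not called as a whole, among them endoplasmic reticulum stress (median difference 0.13 at 24 h, percentile 76.7 of matched random lists) and myeloid transcription factors (percentiles 21.5 at 24 h and 81.5 at the second time). Ddit3 and Trib3, effectors of the integrated stress response, were at 146 and 35.9 RPKM at 24 h against 18.0 and 3.65 RPKM with the empty vector, and at the second time at 5.48 and 2.41 against 4.79 and 3.07 RPKM. Lcn2, an acute-phase gene, was at 219 RPKM at 24 h and 1.98 RPKM at the second time, against 0.106 and 0.084 RPKM. The factor genes Ets2 (43.8 and 13.9 against 2.79 and 3.10 RPKM) and Cebpd (10.4 and 4.90 against 0.637 and 0.696 RPKM) were high at both times. Mef2c, a factor of resting microglia, had 0.806 and 2.25 RPKM against 5.71 and 7.46 RPKM, and Nr4a1 0.236 and 0.678 against 2.77 and 3.96 RPKM. The lysosomal genes Lyz2 (1069.9 and 1397.8 against 592 and 470.4 RPKM) and Ctsd (1175 and 947 against 619 and 436 RPKM) were higher at both times as well, and Edem1, a gene of protein quality control in the endoplasmic reticulum, had 7.70 and 10.7 against 29.7 and 19.4 RPKM. None of these genes passed the threshold over all genes (limma, mutant fragment against empty vector).

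In chromatin, 12.7% of H3K4me2 peaks of mutant-fragment cells overlapped no peak of either other construct, against 7.05% with the empty vector and 5.69% with the wild-type fragment. For C/EBPα and C/EBPβ this share was 44.0% and 35.7% with the wild-type fragment, 13.2% and 13.6% with the mutant fragment, and 16.4% and 9.33% with the empty vector. At Spi1, the gene of PU.1, empty-vector, wild-type-fragment and mutant-fragment cells had 6, 5 and 4 H3K4me2 peaks and 10, 6 and 7 PU.1 peaks within 20 kb of the start. There 1 H3K4me2 peak of mutant-fragment cells (90920923 to 90928800 on chromosome 2) spans 3 empty-vector peaks, so the lower count is no measure of less mark. Of C/EBPα peaks, 29.0%, 23.3% and 32.1% in the same order overlapped PU.1. In primary microglia, few markers of other brain cells were expressed, and their genotype differences included Aldoc (astrocytes) at 0.18, Mbp (oligodendrocytes) at 0.18, Pecam1 (endothelium) at -0.46 and Cd79b (lymphocytes) at -0.48 on the log2(RPKM + 1) scale.

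The higher expression of pro-inflammatory genes in mutant-fragment cells was set against scaling, 1 aberrant library and an effect of any huntingtin fragment. After quantile normalization the list's median log2 fold change was 0.93 (0.96 before), which argues against a scaling difference, and at the second time the list lay at percentile 100 of matched random lists, which argues against the 24 h library as the only source. An effect of any huntingtin fragment as the whole of it is argued against by a median of 1.04 for the mutant against the wild-type fragment. As a part of the rise it stays open, since the list lay at percentile 99.92 for the wild-type fragment against the vector, though with a median of 0.12, and of 0.01 at each time (percentiles 59.0 and 37.6). A hypothesis that the expanded glutamine tract causes the rest could not be separated from a difference in fragment dose, because the table holds no value for the human fragment, and transduction itself, shared by all 3 constructs, was not tested.

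A candidate source of the lower granulocyte genes in mutant microglia is a smaller share of granulocytes in that preparation, a hypothesis weighed with the 11 matched markers S100a8, S100a9, Lcn2, Camp, Ngp, Csf3r, Ltf, Retnlg, Elane, Prtn3 and Mpo. Of these, 8 were at least 2-fold lower, the most abundant being S100a8 (816 and 252 RPKM in wild-type and mutant) and S100a9 (692 and 217 RPKM). That count is part of the pattern itself, so it cannot tell fewer granulocytes from lower expression within the cells. A difference in depth is argued against by the list's place below all lists matched on mean expression (percentile 0). Csf3r at 42.5 and 45.7 RPKM went the other way, 3 of the 11 also passed the expression filter in BV2 cells, and monocyte and border macrophage markers were lower too (median -0.89, 3 of 9 higher). The sort for CD45-low cells is meant to remove granulocytes, though S100a8 was at 816 RPKM in wild-type microglia after it, so its completeness is not known. Lower expression within the sorted cells of the mutant therefore stays open, untested, as does any difference between the 2 preparations, which share their split with the genotype.

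Peaks found in mutant-fragment but not in empty-vector cells lay near raised genes more often than near others in H3K4me2 (7 of the 9 called genes against 23.3% of other genes, adjusted p = 0.00339, Fisher's exact test, two-sided) and in C/EBPα (6 of the 9 against 13.8%, adjusted p = 0.00323), though Pilrb1 and Pilrb2 share 3 H3K4me2 peaks, and with 1 gene per 100 kb it was 6 of 7 (adjusted p = 0.00714) and 4 of 7 (adjusted p = 0.0361). Over the 89 genes at least 2-fold higher at both times the shares were 47.2%, 31.5% and, in PU.1, 62.9% (other genes 44.5%, adjusted p = 0.00297), where the 9 gave 5 (adjusted p = 0.699). Mutant-alone and vector-alone mean alone between these 2 constructs, and such peaks may also occur with the wild-type fragment. Of 9117 C/EBPα peaks of mutant-fragment cells, 6259 overlapped one of empty-vector cells, while 1200 overlapped none of either other construct. One explanation is that raised genes lie where any changed peak is frequent, and for C/EBPα the values over the 89 go with it, since vector-alone peaks were also more frequent there (38.2% against 22.2%, exact adjusted p = 0.00299, and adjusted p = 0.405 for the difference between mutant-alone and vector-alone peaks), while for the 9 it stays open, with vector-alone peaks near 3 (33.3% against 22.2%, exact adjusted p = 0.699). For H3K4me2, vector-alone peaks lay near 24.7% of the 89 (other genes 19.2%) and 2 of the 9, and the exact test of the difference over the 89 gave adjusted p = 0.0722 over 4 antibodies, as it did for PU.1, so the explanations cannot be told apart with this number of genes. Whether these peaks follow or precede the change in expression was not tested, and each antibody has 1 library per construct. Tags per bp differed between the C/EBPα libraries, as given above, and the effect on peaks of 1 construct alone was not tested.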
